A study of Homo sapiens with 12 samples.

How the data were processed

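RNA from 12 libraries of H1299, a human non-small cell lung cancer cell line grown as spheroids, was measured by RNA sequencing. The labels place 3 libraries in each of 4 groups: the non-targeting controls NT1 and NT2, a knockdown of PRKCI (PRKCI_KD) and a knockdown of SOX2 (SOX2_KD), both made with lentiviral short hairpin RNAs. The labels do not say how many hairpins were used per target, so off-target effects of a hairpin cannot be separated from those of the loss of its target. Per the labels' descriptions, NT1 and PRKCI_KD shared a flow cell on lane 8, and NT2 and SOX2_KD shared another flow cell on lane 7. Each knockdown was therefore compared with the control of its own flow cell, and flow cell and pair of groups cannot be separated. Per the labels' protocols, libraries were made from 120 ng of total RNA with a kit that does not mark strand, and both ends were read over 101 bases. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

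The only values used were RPKM, reads scaled by the length of the gene and the reads of the library, which the authors deposited in 1 table with a column per library (per the file headers). Per the submitters' processing notes, the tools were TopHat2 2.1, Bowtie 1.1.2 and featureCounts, with the genome build GRCh38. The gene annotation, the strand setting and the read total behind the denominator are not given in the sources used here. The table held 64253 entries. Of these, 7068 carried a name that occurs more than once and 29 a date in place of a name; the 7091 entries with either were left out of the tests. They held between 3.99% and 4.59% of the reads.

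Read totals and gene lengths were recovered from the deposited RPKM values. For each library a whole read total was found that turned the low values into whole reads at a whole gene length, and the lengths of the other genes were then solved from all libraries together. Of 38880 entries above 0 in at least 3 libraries, 38857 (99.94%) gave whole reads in all libraries at a single length, within 0.001 reads. The denominators lay between 77.1 and 124.3 M reads, and 99.9% of each was found in the listed genes. For the other 23 genes, no length tried gave whole reads in every library. A later search for the length with the most whole libraries went up to 20000 bases. Their number, pathways, direction and spread were examined only after they had been noticed, and the sources used here do not say how those values were made. The results are given with these genes, and where they decide a gene or a list, also without them.

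Expression was tested with limma 3.58.1 (limma-trend, R 4.3.3) on log2(RPKM + 1), with all 12 libraries in a single fit of 4 group means, 8 residual degrees of freedom and 3 prior degrees of freedom. Genes with at least 0.5 RPKM in at least 3 libraries were tested, 19777 in all. P-values were adjusted by the Benjamini-Hochberg method over those genes, with a threshold of 0.05, and the adjusted p of a gene comes from that limma fit unless the text names another setting or a library left out. The design fixed before the data were examined foresaw a count model, with limma-trend as the test for normalized values; as the values are RPKM, limma-trend was used and the level filter was chosen once the unit was known. Log2 fold changes are differences of mean log2(RPKM + 1), so those of genes at low levels are smaller than the ratio of the means. The comparisons were PRKCI_KD against NT1, SOX2_KD against NT2, the difference between those responses, NT2 against NT1, and the overlap of the calls of the knockdowns with Fisher's exact test. With 3 libraries against 3, an exact permutation test of a single gene cannot go below p = 0.1 (two-sided).

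Lists of genes, 31 in all, were written out before the data were examined, and 29 had enough measured members to be tested with camera from limma with a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were run beside it, adjusted over the lists. Fry tests whether a list's genes move, on balance, in a single direction and does not compare them with other genes. Counts of list members are given over all genes tested and, where they differ, adjusted over the list alone. The level filter took all 12 libraries together, so the measured members include genes near 0 RPKM in a whole pair of groups. Such genes cannot fall in that pair, and in the difference between the responses their value comes almost wholly from the other pair. Examples are TGFBI, SPARC, AXL, CD44 and BOC in NT2 and SOX2_KD, and ALDH1A1 in NT1 and PRKCI_KD.

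The genes named were chosen by a rule fixed before the data were examined: the targeted genes; the 10 highest and 10 lowest changes per knockdown among genes past the threshold whose 3 knockdown libraries all lay beyond the 3 controls; up to 4 members of each list; the genes shared by both knockdowns, 8 per direction and 4 per opposite direction; the 5 highest and 5 lowest differences between the responses; and the 3 highest and 3 lowest between the controls. The level of at least 1 on the log2 scale was applied as mean log2(RPKM + 1). Names with a non-coding pattern (such as LOC, LINC, MIR, SNOR or an ending in -AS) and clone-style and pseudogene-like names were passed over. Other non-coding genes, such as NEAT1, SNHG19 and mitochondrial transfer RNA genes, were kept. By its wording the rule also dropped genes such as BNIP3, MMP1, TIMP1 and CRABP2 from the top changes. Names ending in _ and a digit were passed over by a choice made after the values were seen, and genes on the Y chromosome and XIST were not considered. Gene positions are 1-based on GRCh38, from a GENCODE annotation matched by symbol, and were found for 187 of the 189 named genes.

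The test was tried on simulated reads drawn from the real means, with 200 genes changed. The changed genes came from those at 1 RPKM or more in the control. All genes had the same dispersion and were drawn independently. The shares below therefore do not cover genes at lower levels or a spread that genes have in common. For PRKCI_KD against NT1, among 19245 genes, it recovered 89.6% of 1.5-fold changes and all of the larger ones, with 12 false calls (5.9% of calls). For SOX2_KD against NT2, among 19256 genes, it recovered 82.1% of 1.5-fold, 100% of 2-fold and 98.5% of 4-fold changes, with 9 false calls (4.6%). Replicate libraries differed by more than counting noise, with a chi-square per degree of freedom between 3.84 and 82.9 for pairs within a group.

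The replicate numbers come from the sample titles. Deviations from the group means of same-numbered libraries correlated across genes at 0.51, 0.24 and 0.24 between NT2 and SOX2_KD, which was taken as pairing, and at 0.49, -0.11 and 0.34 between NT1 and PRKCI_KD, which was not. However, NT2 replicate 3 and SOX2_KD replicate 2 also correlated at 0.24, and NT2 replicate 2 and SOX2_KD replicate 3 at 0.13. These values set replicate 1 apart but do not pair replicates 2 and 3 by number. On the main axis of deviations within groups, with 43.6% of that variance, replicate 1 had the lowest score in each group. Its scores were -0.39 in NT1, -0.33 in PRKCI_KD, -0.40 in NT2 and -0.30 in SOX2_KD. The main fit left this shared deviation in the residual spread, and its source was not tested. Alternatives fixed before the data were examined were quantile normalization, other level filters, voom (limma) on the recovered reads, each pair of groups alone, the replicate number as a block, leaving out each library, an adjusted p of 0.01, limma's treat against 1.5-fold, and pseudocounts of 0.1 and 5. Those chosen after seeing the data were median-of-ratios scaling of the RPKM values, keeping the left-out entries, removing the trend with GC content and transcript length, restricting the overlap to genes expressed in both controls, and leaving out the genes without whole reads. GC content and length were found for 77.3% of the genes tested, so that correction was restricted to genes without clone-style names, of which 99.3% had them, a choice made after a first result had been seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the remaining steps, and matplotlib 3.10.9 drew the plots.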

Results

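RNA sequencing measured gene expression in spheroids of H1299 cells with PRKCI silenced, with SOX2 silenced, or carrying a non-targeting hairpin. PRKCI encodes atypical protein kinase C iota, a kinase of cell polarity, and SOX2 encodes a transcription factor of stem cells; both genes lie on the long arm of chromosome 3. Each of the 4 groups held 3 libraries, and PRKCI_KD was set against NT1 and SOX2_KD against NT2. The recovered read totals were 118.87, 94.89 and 97.91 M reads for NT1, 93.52, 94.86 and 87.36 M reads for PRKCI_KD, 91.67, 109.24 and 77.05 M reads for NT2, and 124.22, 92.21 and 82.72 M reads for SOX2_KD. The 10 most abundant entries took between 3.79% and 7.08% of the reads of a library. Correlations of log2(RPKM + 1) between libraries across genes were 0.964 to 0.995 within the pair of NT1 and PRKCI_KD, 0.989 to 0.997 within the pair of NT2 and SOX2_KD, and 0.826 to 0.838 across the pairs.

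Most of the deposited values were whole reads at a single length per gene, and 23 genes were exceptions: ADAM17, ADCY10, ADCY3, BMP7, CNTN1, FGFR2, FZD7, GLI1, GLI2, GLIS1, GNB3, HEY1, HHAT, LEF1, MMP2, NOTCH3, RAC3, SMO, SOX2, WNT11, WNT3A, WNT5B and WNT9A. They include ligands, receptors and transcription factors of the Hedgehog, Wnt and Notch pathways. For 19 of them a single length made at least 5 libraries whole while others were not, in 67 of 220 values above 0, within 0.001 reads. Of the 23 genes, 19 passed the level filter, and all 19 had lower means in both knockdowns than in their controls, against 36.4% of the 19758 other genes tested (Fisher's exact test across genes, two-sided, p = 4.67e-09). The values of FGFR2 corresponded to 2150, 1270 and 1320 reads in NT1 and 7470, 9010 and 6330 reads in NT2. All 6 are multiples of 10, which none of the 14827 other genes with at least 100 reads in each control library showed. Values of SOX2 in SOX2_KD corresponded to 163.5 reads in replicate 1, 135 in replicate 2 and 122.4 in replicate 3. Statements on these genes, and on the lists that hold them, carry that limit.

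**Figure D1:**
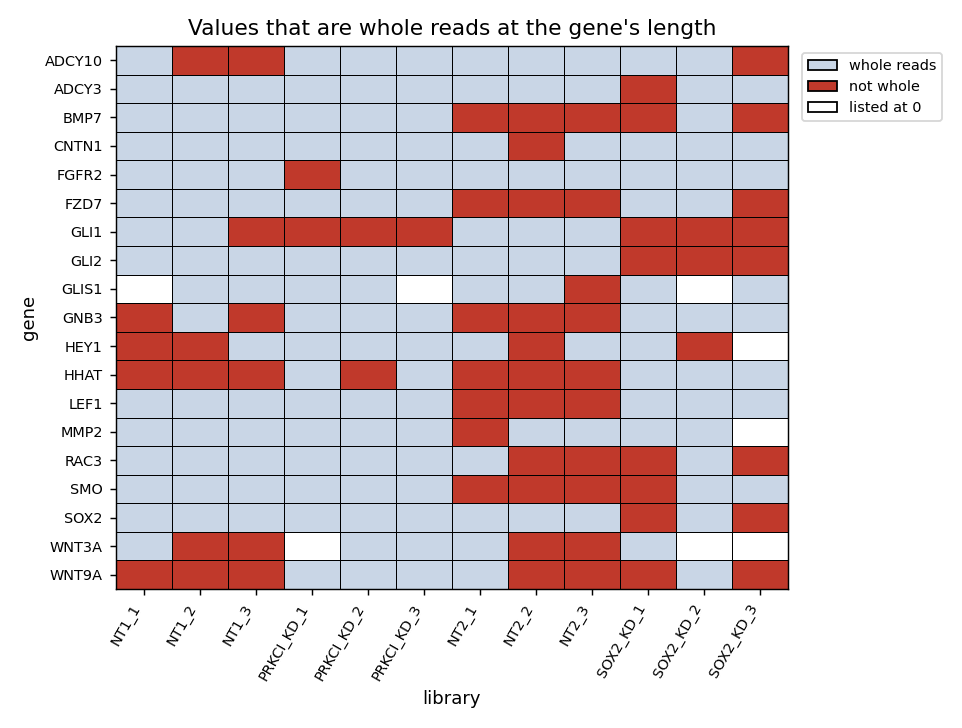
Deposited values of the genes for which a single length makes at least 5 libraries whole reads, with a row per gene and a column per library. Blue cells are whole reads within 0.001 reads, red cells are not, and white cells are listed at 0; 67 of the 220 values above 0 are red.

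The targeted genes were read first, as a check of the labels. PRKCI (chromosome 3, 170222365 to 170305981) fell from 14.8 ± 1.40 RPKM in NT1 to 2.50 ± 0.08 RPKM in PRKCI_KD (mean ± SD, n = 3), a log2 fold change of -2.18 (SE 0.09, adjusted p = 1.52e-08). SOX2 (chromosome 3, 181711924 to 181714436) fell from 1.48 ± 0.07 RPKM in NT2 to 0.56 ± 0.04 RPKM in SOX2_KD, a log2 fold change of -0.66 (SE 0.06, adjusted p = 2.19e-04), with values that were not whole reads in 2 of the 3 knockdown libraries. SOX2 lies within the overlapping non-coding gene SOX2-OT, so its reads could be shared with that gene. SOX2 also fell in PRKCI_KD, from 3.01 to 2.02 RPKM (log2 fold change -0.41, SE 0.06, adjusted p = 2.51e-04). PRKCI was at 16.7 RPKM in NT2 and 16.1 RPKM in SOX2_KD (log2 fold change -0.05, SE 0.09, adjusted p = 0.789). The log2 fold change of SOX2 in SOX2_KD depends on the pseudocount at these low levels, with -1.25 at 0.1 and -0.22 at 5.

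**Figure D2:**
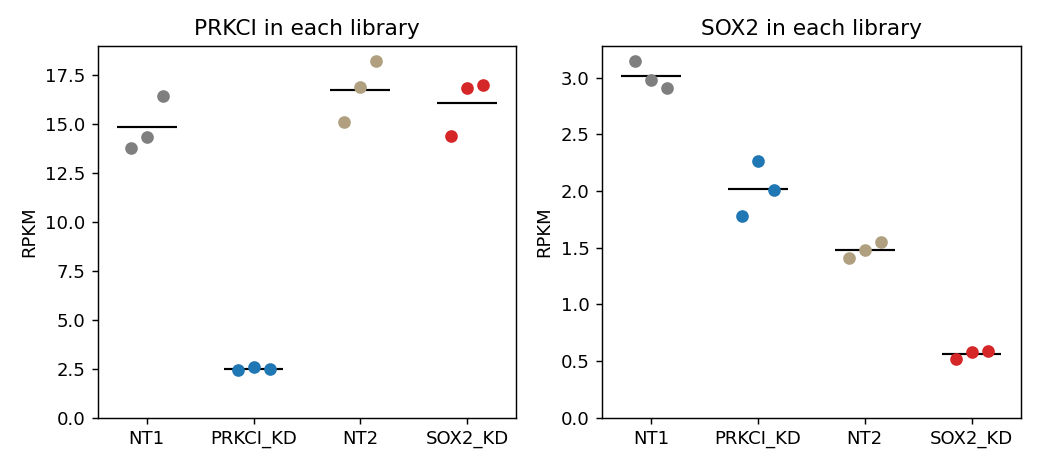
RPKM of PRKCI (left) and SOX2 (right) in each library, with a point per library and a line at the mean of each group of 3. PRKCI lies between 2.43 and 2.58 RPKM in PRKCI_KD and at 13.77 RPKM or more in the other groups, and SOX2 lies between 0.52 and 0.59 RPKM in SOX2_KD and between 1.41 and 1.55 RPKM in NT2.

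In PRKCI_KD, genes of the response to low oxygen, of the interferon response and of the unfolded protein response were higher than in NT1. All 22 measured hypoxia response genes and all 24 measured interferon response genes rose, and 33 of 34 cell cycle genes fell, a list with adjusted p = 0.0598 with an estimated correlation. The immediate early genes FOS and FOSB, which encode parts of the AP-1 transcription factor, rose from 2.28 ± 1.83 to 43.5 ± 1.89 RPKM (mean ± SD, n = 3) and from 1.11 to 20.8 RPKM. NT1 replicate 3, at 4.39 RPKM, raised the FOS mean of NT1, and without it the log2 fold change of FOS was 4.32 in place of 3.90. SOX4, a transcription factor of progenitor cells, fell from 52.5 to 7.39 RPKM. The comparison asked which transcripts differ between PRKCI_KD and NT1.

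In PRKCI_KD against NT1, 8928 of 19777 genes passed the threshold, 3589 higher and 5339 lower, and 399 of them changed at least 2-fold (242 higher, 157 lower). The median log2 fold change over all genes was -0.036. Among the 10 named highest changes, SLC2A3, a neuronal-type glucose transporter, rose by 3.58 on the log2 scale (SE 0.05, adjusted p = 8.75e-12), and its near-identical neighbour SLC2A14, whose reads cannot be told apart with certainty, by 3.39. The glycolytic genes PFKFB4, HK2 and GPI rose by 3.20, 2.93 and 2.90. P4HA1, a collagen prolyl hydroxylase, and ERO1L, an oxidase of the endoplasmic reticulum, rose by 3.36 and 3.14. FOS rose by 3.90 (SE 0.26, adjusted p = 7.91e-07), FOSB by 3.40, and IFITM1, an interferon-induced membrane protein, by 2.75. Besides PRKCI, the lowest changes included those of SOX4 (-2.66, SE 0.10, adjusted p = 7.78e-09), CLU, which encodes clusterin (-2.17), CRH, the corticotropin-releasing hormone (-2.07), TCF7 (-1.84), ID1 (-1.82), NPTX2 (-1.65), ID2 (-1.59) and FN1, which encodes fibronectin (-1.57).

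The lists of stress genes moved upward. In the hypoxia list, SLC2A3, HK2, VEGFA, an angiogenic factor (2.62), and NDRG1 (2.20) had the smallest p-values, and the list stood apart in camera (adjusted p = 1.21e-26, and adjusted p = 7.09e-04 with an estimated correlation). Of 20 genes of the unfolded protein and integrated stress response, 18 rose and 2 did not pass (adjusted p = 2.57e-16, and adjusted p = 7.09e-04 with an estimated correlation). Examples were the chaperone HSPA5 (1.86), HERPUD1 (1.60), TRIB3 (2.51) and ATF3 (2.15). The 24 interferon response genes included OAS2 (1.85), IFI44L (1.64) and OAS3 (1.45), and the list had adjusted p = 1.04e-22, and adjusted p = 0.00442 with an estimated correlation. Of 23 genes of cholesterol and fatty acid synthesis, 13 rose, among them INSIG1 (1.67), MSMO1 (1.43) and SCD (0.97), and 3 fell, with adjusted p = 7.05e-04, and adjusted p = 0.0244 with an estimated correlation. Of 9 epithelial genes, 5 rose, among them the tight junction gene CLDN1 (1.24) and the desmosome gene DSP (0.48), with adjusted p = 0.0014 (0.0802 without the level filter), and adjusted p = 0.0419 with an estimated correlation.

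Further lists passed with the preset correlation and not with an estimated one. Of 16 AP-1 and immediate early genes, 11 rose, among them FOSB, ATF3, DUSP1 (1.23) and NR4A1 (1.70), and 2 fell (adjusted p = 1.8e-06, and adjusted p = 0.134 with an estimated correlation). Of 17 YAP and TEAD targets, 9 rose, including CYR61 (2.51), AMOTL2 (1.30), LATS2 (1.22) and CTGF (1.18), and 5 fell (adjusted p = 0.00456, and adjusted p = 0.0598 with an estimated correlation). Of 11 NF-kB and cytokine genes, 7 rose, such as ICAM1 (1.45) and CCL2 (0.60), and 1, LIF (-0.72), fell (adjusted p = 0.00259, and adjusted p = 0.0628 with an estimated correlation). Of 18 ribosomal protein genes, 15 rose, such as RPL18 (0.59), but only 6 did so with quantile normalization (adjusted p = 1.2e-06, and adjusted p = 0.143 with an estimated correlation). The cell cycle genes that fell included the mitotic regulators FOXM1 (-1.19) and PLK1 (-1.12) and the replication genes MCM4 (-1.04) and MCM3 (-1.03), with adjusted p = 2.02e-17, and adjusted p = 0.0598 with an estimated correlation. Of 13 mitochondrially encoded genes, 11 fell, among them MT-CO1 (-0.73) and MT-ATP6 (-0.73), with adjusted p = 5.83e-05, and adjusted p = 0.249 with an estimated correlation. Mitochondrial entries took 2.63% to 3.15% of the reads in PRKCI_KD and 3.42% to 3.74% in NT1.

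Wnt targets and Hedgehog genes passed with the preset correlation and not with an estimated one. Of 9 Wnt targets, 6 fell, including TCF7, AXIN2 (-1.47), LEF1 (-1.18) and CCND1 (-0.68), and 1 rose (adjusted p = 0.0014, and adjusted p = 0.0896 with an estimated correlation); without LEF1, whose values were not all whole reads, 5 of 8 fell (adjusted p = 0.00506). Of 15 Hedgehog pathway genes, 10 fell, such as KIF7 (-0.60), GLI1 (-0.64), HHAT (-0.50) and GLI3 (-0.50), with adjusted p = 0.00231, and adjusted p = 0.355 with an estimated correlation. GLI1, GLI2, HHAT and SMO are among the genes without whole reads, and without them 6 of 11 Hedgehog genes fell (adjusted p = 0.0488). Of 7 genes reported as PKC-iota effectors, 4 fell: NOTCH3 (-0.43), HHAT, SOX2 and ECT2 (-0.47), with adjusted p = 0.265; ECT2 lost its call without PRKCI_KD replicate 1 (adjusted p = 0.0538), and without the genes that lack whole reads 1 of 4 fell.

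The other lists did not pass in camera, except that without the level filter TGF-beta and BMP signalling (adjusted p = 0.0174) and ribosome biogenesis (0.0204) passed as lower. In the atypical PKC polarity complex, 5 of 15 genes fell, including the target and the small GTPase gene CDC42 (-0.76), and 3 rose, including INADL (0.35) and PARD3 (0.31), with adjusted p = 0.979. Of 13 stem cell factors, 6 fell, among them ABCG2 (-1.72), CD24 (-1.20) and SOX9 (-0.90), and 2 rose, among them KLF4 (0.82), with adjusted p = 0.265. The list of chromosome 3q26 neighbours holds the target PRKCI itself and SOX2, which lacks whole reads. Of its 23 measured genes, 10 fell, among them PRKCI, SOX2, TNIK (-1.20) and MECOM (-0.87). The 4 that rose included GPR160 (0.77), and the list had adjusted p = 0.277. In TGF-beta and BMP signalling, 10 of 21 fell, among them ID1, ID2 and ID3 (-1.54), and 3 rose, among them SMAD7 (0.54), with adjusted p = 0.201. In Notch signalling, 7 of 18 rose, among them HES4 (1.33) and HES1 (0.54), and 4 fell, among them JAG1 (-0.77), with adjusted p = 0.467. The list holds NOTCH3 and HEY1, which lack whole reads, and had adjusted p = 0.299 without them. In ribosome biogenesis, 10 of 19 fell, among them POLR1A (-0.78) and UTP20 (-0.79), and 4 rose (adjusted p = 0.201). Of 18 mesenchymal genes, 9 fell, among them FN1 and TGFBI (-1.16), and 4 rose, with adjusted p = 0.56. Of 14 matrix metalloproteinases and inhibitors, 6 fell, among them MMP16 (-1.01) and MMP2 (-0.68, without whole reads in every library), and 5 rose, among them MMP9 (0.73) and TIMP1 (0.69), with adjusted p = 0.959. Among MAPK output genes, 7 of 15 fell, such as SPRY1 (-0.95), and 4 rose, such as EGR1 (2.01) and DUSP5 (1.82), with adjusted p = 0.675. Among p53 targets, 6 of 16 rose, such as GDF15 (1.42) and TNFRSF10B (0.79), and 7 fell, such as TP53INP1 (-0.61), with adjusted p = 0.804. Among NRF2 targets, 5 of 15 rose, such as HMOX1 (2.47), and 4 fell, such as PGD (-0.49), with adjusted p = 0.265.

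Few lineage markers were measured. Of 4 squamous markers, KRT15 (0.68) and S100A2 (0.34) rose and PTHLH (-0.97) fell (adjusted p = 0.343). Of 4 airway and alveolar markers, LAMP3 (0.41) rose and NKX2-1 (-0.16) fell (adjusted p = 0.612), and NKX2-1 lost its call without NT1 replicate 1 (adjusted p = 0.0584), NT1 replicate 2 (0.0729), PRKCI_KD replicate 2 (0.103) or PRKCI_KD replicate 3 (0.0577). Of 7 neuroendocrine and neural markers, 2 rose, among them the glycolytic enzyme gene ENO2 (2.61), and 3 fell, among them SNAP25 (-1.33) and UCHL1 (-0.91), with adjusted p = 0.546. Of 6 fibroblast markers, TAGLN (0.47) rose and COL1A1 (-0.26) fell (adjusted p = 0.831). No endothelial marker passed the level filter, and of the immune cell markers CD68 alone did (log2 fold change 0.19, adjusted p = 0.0768). Adjusted over the list alone, counts differed from those given in the Hedgehog list (1 higher, 11 lower), epithelial genes (6 higher), mesenchymal genes (5 higher), lipid synthesis (4 lower), YAP targets (10 higher), TGF-beta signalling (4 higher), airway markers (2 higher), neural markers (4 lower), immune markers (1 higher), mitochondrially encoded genes (12 lower) and ribosomal proteins (16 higher). Median, mean and camera direction differed in sign for matrix metalloproteinases (0.03, -0.10, up), MAPK output (-0.09, 0.05, down), p53 targets (-0.08, 0.04, up) and fibroblast markers (-0.02, 0.02, up).

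SOX2_KD differed from NT2 in fewer genes, among them the immediate early genes FOS, EGR1 and FOSB, which encode transcription factors, and 3 metallothionein genes, which encode metal-binding proteins. FOS, EGR1 and FOSB fell from 40.1 to 5.55 RPKM, from 91.5 to 14.2 RPKM and from 7.15 to 0.65 RPKM. The YAP target genes CYR61 and CTGF, which encode secreted matrix-associated proteins, fell by 1.26 and 1.05 on the log2 scale. IFITM1 rose from 32.5 to 66.9 RPKM, and the metallothionein genes MT1E, MT1X and MT2A rose by 0.83, 0.76 and 0.69. The comparison asked which transcripts differ between SOX2_KD and NT2.

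In SOX2_KD against NT2, 1618 of 19777 genes passed, 705 higher and 913 lower, and 17 of them changed at least 2-fold (5 higher, 12 lower). The median log2 fold change over all genes was -0.016. With quantile normalization 741 were higher and 573 lower, and with median-of-ratios scaling 899 were higher and 723 lower, so that scaling decides the balance of directions. With the replicate number as a block, which treats same-numbered libraries as pairs, 3419 genes passed. The count fell to 681 without SOX2_KD replicate 3, to 691 without SOX2_KD replicate 2, to 1075 without SOX2_KD replicate 1, to 856 without NT2 replicate 2 and to 903 without NT2 replicate 3. The 5 genes at least 2-fold higher, listed after their values were seen, were CRABP2, NES, IFITM1, SNORA56 and HOTAIRM1_2. CRABP2, a retinoic acid binding protein gene, was at 4.32 RPKM in NT2 and 25.6 RPKM in SOX2_KD, beside 27.2 RPKM in NT1 and 23.8 RPKM in PRKCI_KD (log2 fold change 2.32, SE 0.05, adjusted p = 1.23e-09).

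Of the 10 named highest changes, IFITM1 rose by 1.02 (SE 0.06, adjusted p = 8.99e-06), ARL14 by 0.94, NEAT1, a long non-coding RNA of nuclear paraspeckles, by 0.76, GABRE by 0.69 and MT-ND4 by 0.67. MT-ND4L (0.67), which overlaps MT-ND4, lost its call without NT1 replicate 1 (adjusted p = 0.058) or 2 (0.0653), PRKCI_KD replicate 1 (0.0545) or 2 (0.0618), NT2 replicate 1 (0.0596) or 3 (0.0554), or SOX2_KD replicate 1 (0.0939), 2 (0.133) or 3 (0.131). STC1 (0.71) lost it without NT2 replicate 1 (adjusted p = 0.053) or 2 (0.0595) and without SOX2_KD replicate 2 (0.0595) or 3 (0.0673). The 10 lowest held FOS (-2.65, SE 0.26, adjusted p = 3.55e-04), EGR1 (-2.60, SE 0.12, adjusted p = 8.14e-07), FOSB (-2.30), CYR61 and CTGF. They also held the mitochondrial transfer RNA genes MT-TA (-1.33), MT-TV (-1.06), MT-TM and MT-TF (-1.30), and MT-TF lost its call without NT2 replicate 2 (adjusted p = 0.0598) or 3 (0.0583) and without SOX2_KD replicate 1 (0.0518) or 3 (0.0541). FGFR2, a fibroblast growth factor receptor gene, was at 10.95 RPKM in NT2 and 0.97 RPKM in SOX2_KD (log2 fold change -2.60, SE 0.07, adjusted p = 6.44e-09), where all control values are multiples of 10 reads.

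Of the lists, 9 passed in camera with the preset correlation and 20 with fry; none passed in camera with an estimated correlation, with 7 at an unadjusted p under 0.05. Of 16 AP-1 and immediate early genes, 10 fell, among them FOS, EGR1, FOSB and DUSP1 (-0.92), and 1 rose (adjusted p = 1e-06, and adjusted p = 0.177 with an estimated correlation). Of 22 hypoxia response genes, 7 rose, among them SLC2A3 (0.55) and HK2 (0.37), and 15 did not pass (adjusted p = 1e-06, and adjusted p = 0.0534 with an estimated correlation). Of 34 cell cycle genes, 8 fell, among them TYMS (-0.57) and FOXM1 (-0.34), and 2 did so with quantile normalization (adjusted p = 3.46e-07, and adjusted p = 0.276 with an estimated correlation). Of 13 mitochondrially encoded genes, 10 rose, among them MT-ND4 and MT-CO1 (0.46), but none passed with quantile normalization (adjusted p = 2.47e-11, and adjusted p = 0.161 with an estimated correlation). Mitochondrial entries took 5.91% to 6.14% of the reads in SOX2_KD and 4.12% to 4.97% in NT2. Of 18 ribosomal protein genes, 5 rose, such as RPL4 (0.37), with adjusted p = 4.69e-08, and adjusted p = 0.161 with an estimated correlation. Of 14 matrix metalloproteinases and inhibitors, 5 fell, among them MMP1 (-0.99), MMP10 (-0.95) and MMP9 (-0.67), with adjusted p = 0.00243, and adjusted p = 0.161 with an estimated correlation. Of 9 epithelial genes, 2 rose (adjusted p = 0.0298, and adjusted p = 0.161 with an estimated correlation). The list lost its call without NT2 replicate 3 (adjusted p = 0.0816) or SOX2_KD replicate 1 (0.065).

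The next lists hold genes without whole reads and were also tested without those genes. Of 7 reported PKC-iota effectors, 4 fell: HHAT (-0.77), MMP10, NOTCH3 (-0.61) and the target SOX2 (adjusted p = 3.96e-07, and adjusted p = 0.0534 with an estimated correlation). Without HHAT, NOTCH3 and SOX2, 1 of 4 fell, MMP10 (adjusted p = 0.01). Of 9 Wnt targets, 2 fell, LEF1 (-0.61) and TCF7 (-0.20), with adjusted p = 0.013, and adjusted p = 0.206 with an estimated correlation. The Wnt list lost its call without LEF1 (adjusted p = 0.0817), with the replicate block (0.0526) and without NT2 replicate 1 (0.0623). TCF7 lost its call without NT2 replicate 1 (adjusted p = 0.0608), 2 (0.0775) or 3 (0.0737) and without SOX2_KD replicate 1 (0.0632), 2 (0.103) or 3 (0.0852). Of 15 Hedgehog genes, 4 fell, HHAT, SMO (-0.52), GLI1 (-0.44) and GLI2 (-0.22), with adjusted p = 0.0503, and adjusted p = 0.635 with an estimated correlation. All 4 are genes without whole reads; among the 11 others none passed in limma, with 1 at an unadjusted p under 0.05, and camera gave adjusted p = 0.917 for them. The 11 include BOC, at 0.04 RPKM in both NT2 and SOX2_KD, which could hardly fall. The full list passed with median-of-ratios scaling (adjusted p = 0.037), without the level filter (0.0327), and without PRKCI_KD replicate 1 (adjusted p = 0.0495) or 3 (0.0439), NT2 replicate 3 (0.0467), or SOX2_KD replicate 1 (0.0321) or 3 (0.0498).

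The remaining lists did not pass in camera, except that without the level filter mesenchymal genes (adjusted p = 0.0211), MAPK output (0.0307), Notch signalling (0.0315) and the unfolded protein and stress response (0.0315) passed as lower. Of 24 interferon response genes, 5 fell, among them OASL (-0.90), IFIT1 (-0.84) and IFIT3 (-0.82), and 2 rose, among them IFITM1 (adjusted p = 0.585). Of 20 genes of the unfolded protein and integrated stress response, 4 fell, among them PSAT1 (-0.39) and PDIA4 (-0.26), and 3 rose (adjusted p = 0.251). Among YAP and TEAD targets, 3 of 17 fell, including CYR61 and CTGF (adjusted p = 0.703). Among MAPK output genes, 2 of 15 fell, EGR1 and DUSP6 (-0.83), and 2 rose, among them SPRY1 (0.46), with adjusted p = 0.115; this list passed without NT1 replicate 2 (adjusted p = 0.0155). In Notch signalling, 3 of 18 fell, among them JAG1 (-0.51) and NOTCH3 (adjusted p = 0.312). NOTCH3 and HEY1 of this list lack whole reads, and without them the list had adjusted p = 0.666. The pass without the level filter included these genes. Of 21 TGF-beta and BMP genes, BMP7 (-0.47, without whole reads) and SMAD7 (-0.39) fell and 1 rose (adjusted p = 0.585). Of 13 stem cell factors, NES (1.19) rose and 2 fell, among them SOX2 (adjusted p = 0.778). CD44 of this list was at 0 RPKM in NT2 and could not fall. Of 23 genes in the chromosome 3q26 list, TNIK (0.27) rose and 3 fell, among them the target SOX2 (adjusted p = 0.468). In the polarity complex, PARD6G (-0.31) fell and 1 of 15 rose (adjusted p = 0.573). Of 23 lipid synthesis genes, 2 rose, among them SCD (0.33), and 1 fell (adjusted p = 0.245). Of 15 NRF2 targets, ABCC2 (0.40) rose and 1 fell (adjusted p = 0.778). Of 18 mesenchymal genes, 1 fell (adjusted p = 0.131), and VIM had a log2 fold change of -0.12 (adjusted p = 0.34). The 18 include TGFBI and SPARC, at 0 and 0.01 RPKM in NT2, which could not fall. Of 11 NF-kB and cytokine genes, 1 fell (adjusted p = 0.885). None of 19 ribosome biogenesis genes and none of 16 p53 targets passed in limma, with 1 gene of each at an unadjusted p under 0.05 (adjusted p = 0.667 and 0.585 for the lists in camera). NCL was at -0.09 (adjusted p = 0.485) and TNFRSF10B at 0.09 (adjusted p = 0.234).

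Of the lineage markers in SOX2_KD, KRT15 (-0.51) fell among 4 squamous markers (adjusted p = 0.585), 1 of 4 airway markers rose (adjusted p = 0.294) and 1 of 7 neural markers rose (adjusted p = 0.585). Among 6 fibroblast markers FAP (0.37) rose and 2 fell, among them PDGFRA (-0.31), with adjusted p = 0.616. CD68, the immune marker measured, rose by 0.32 (adjusted p = 0.0371); it lost its call without NT1 replicate 2 (0.0546), PRKCI_KD replicate 2 (0.0543), NT2 replicate 2 (0.127) or 3 (0.108), or SOX2_KD replicate 1 (0.119), 2 (0.0754) or 3 (0.0788). Adjusted over the list alone, counts differed from those given in the Hedgehog list (5 lower), Wnt targets (4 lower), cell cycle (13 lower), hypoxia response (10 higher), stress response (8 lower), interferon response (4 higher, 6 lower), NF-kB genes (1 higher), MAPK output (3 higher, 8 lower), YAP targets (1 higher, 4 lower), AP-1 genes (3 higher), TGF-beta signalling (3 lower), airway markers (2 higher), mitochondrially encoded genes (13 higher) and ribosomal proteins (11 higher). Median, mean and camera direction differed in sign for YAP targets (0.01, -0.12, down), squamous markers (0.03, -0.08, down), p53 targets (-0.01, 0.01, up), NF-kB genes (-0.01, -0.02, up), NRF2 targets (-0.01, -0.01, up) and stem cell factors (0, 0.01, down).

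**Figure D3:**
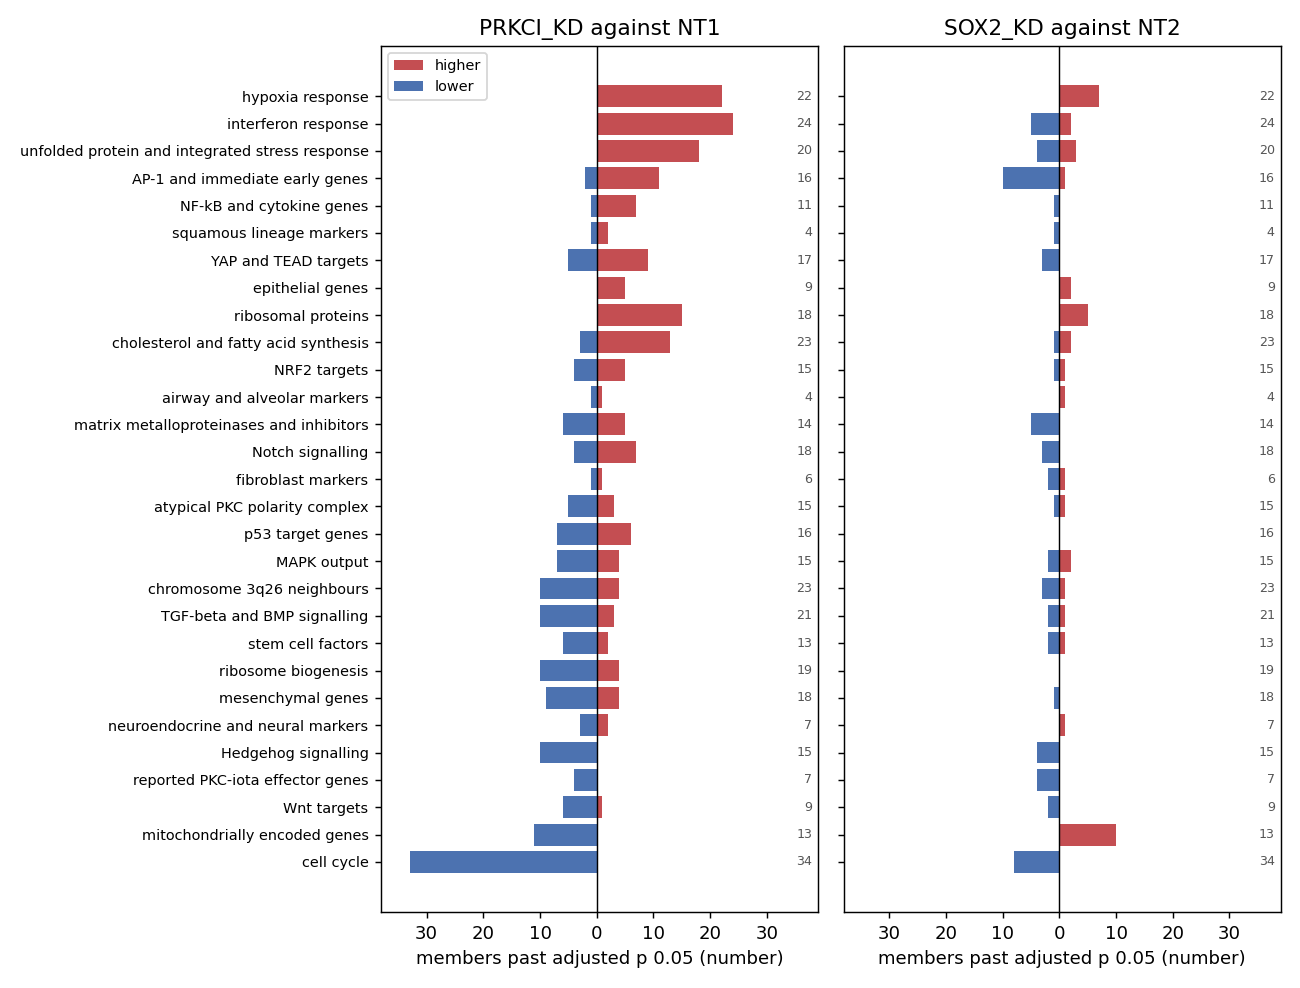
Number of members higher (red, to the right of 0) and lower (blue, to the left) past adjusted p 0.05 in each list with at least 4 measured members, for PRKCI_KD against NT1 (left) and SOX2_KD against NT2 (right). The number measured stands at the right edge of each panel, and all 22 hypoxia genes were higher in PRKCI_KD.

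The responses to the knockdowns differed in many genes, and some moved in opposite directions. FOS, FOSB, EGR1 and CYR61 rose with PRKCI silenced and fell with SOX2 silenced, with differences between the log2 responses of 6.55 (SE 0.37, adjusted p = 6.32e-07), 5.70, 4.61 and 3.76. SLC2A3 rose in both, by 3.03 more in PRKCI_KD. SOX4 (-2.46), CLU (-2.26), ID1 (-2.24), CRH (-2.13) and PRKCI (-2.12) had the lowest differences, and CLU and CRH were under 1 RPKM in NT2 and SOX2_KD. The responses start from unlike controls: of 16 AP-1 and immediate early genes, 11 were higher in NT2 than in NT1 and 3 lower. The targeted gene cannot be separated from the pair of groups. Opposite directions therefore do not show that PRKCI and SOX2 act oppositely in the same cells.

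The difference between the responses passed in 5155 genes, 2224 of them with a higher response in PRKCI_KD than in SOX2_KD and 2931 with a lower one. All 22 hypoxia genes (adjusted p = 5.6e-32, and adjusted p = 2.84e-04 with an estimated correlation), 17 of 20 unfolded protein and stress response genes (adjusted p = 1.15e-20, and adjusted p = 2.84e-04 with an estimated correlation) and 22 of 24 interferon genes (adjusted p = 5.96e-27, and adjusted p = 0.00246 with an estimated correlation) responded more upward in PRKCI_KD. Of 34 cell cycle genes 32 responded more downward (adjusted p = 2.21e-17, and adjusted p = 0.0607 with an estimated correlation), as did all 13 mitochondrially encoded genes (adjusted p = 4.5e-10, and adjusted p = 0.0853 with an estimated correlation). Of 16 AP-1 and immediate early genes, 13 were higher and 2 lower (adjusted p = 1.37e-11, and adjusted p = 0.0566 with an estimated correlation), of 23 lipid synthesis genes 10 were higher and 1 lower (adjusted p = 0.00184, and adjusted p = 0.0339 with an estimated correlation), and of 9 Wnt targets 6 were lower (adjusted p = 0.00324, and adjusted p = 0.099 with an estimated correlation). Adjusted over the list alone, 18 stress response genes, 33 cell cycle genes in the lower direction, 3 AP-1 genes in the lower direction, 12 lipid synthesis genes in the higher direction and 1 Wnt target in the higher direction passed, with the other counts as given. Reported PKC-iota effectors also passed with a positive difference (3 of 7 higher, 4 adjusted over the list alone, 0 lower, adjusted p = 0.0255 in camera). In each knockdown 4 of the 7 fell and 0 rose, with a median log2 fold change of -0.41 in PRKCI_KD and -0.61 in SOX2_KD. The difference is thus a smaller fall in PRKCI_KD, not a rise. That list holds genes without whole reads. YAP and TEAD targets (adjusted p = 0.00324), NF-kB and cytokine genes (0.00324), epithelial genes (0.0255) and ribosomal proteins (0.0499) passed in camera with a positive difference as well. None of these further lists passed with an estimated correlation. When libraries were regrouped within each pair, 8 other splits that kept NT1 apart from PRKCI_KD gave 3898 to 5700 genes and 91 that mixed them gave 30 at most, so the count mainly follows the PRKCI_KD labels.

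IFITM1, NEAT1 and the metallothionein gene MT1X rose in both knockdowns, and the histone genes HIST1H2AM and HIST1H3J fell in both. Of the 8 named shared higher genes, GABRE rose by 1.16 in PRKCI_KD and 0.69 in SOX2_KD, PNISR by 0.55 and 0.61, and GOLGA8B by 0.61 and 0.54. SNHG19 (0.72 and 0.60) lost its call in SOX2_KD without NT2 replicate 2 (adjusted p = 0.061) or 3 (0.0608) or SOX2_KD replicate 3 (0.0667). HIST1H2AM fell by 0.74 and 0.97 and HIST1H3J by 0.68 and 0.82; they belong to a family of near-identical copies, so their reads are uncertain. FGFR2 (-1.41 and -2.60) and LEF1 (-1.18 and -0.61) were also lower in both, and neither has whole reads in all libraries. MT-CO1 and SPRY1 fell in PRKCI_KD and rose in SOX2_KD, where MT-CO1 did not pass with quantile normalization (adjusted p = 0.127).

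In all, 834 genes changed in the same direction in both knockdowns, 332 higher (127.9 if the lists were independent) and 502 lower (246.5). With quantile normalization 387 were higher and 259 lower, and with median-of-ratios scaling 451 were higher and 354 lower, so that the balance of directions turns with scaling. The odds ratios were 4.32 and 3.54 (Fisher's exact test, two-sided, adjusted p = 7.32e-72 and 5.4e-74), across genes that are not independent replicates. Opposite changes were fewer than independent lists give, with 110 higher in PRKCI_KD and lower in SOX2_KD (165.7) and 70 the other way (190.3). The controls are not shared, so the log2 fold changes of the knockdowns have no library in common. The calls do share an estimate of spread, which comes from the single fit of all 12 libraries. Across all genes tested the log2 responses correlated with Pearson's r of 0.236 and Spearman's rho of 0.321. The shared count was 1934 with the replicate block. It was 328 without SOX2_KD replicate 3, 340 without SOX2_KD replicate 2, 545 without SOX2_KD replicate 1, 420 without NT2 replicate 2 and 455 without NT2 replicate 3.

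**Figure D4:**
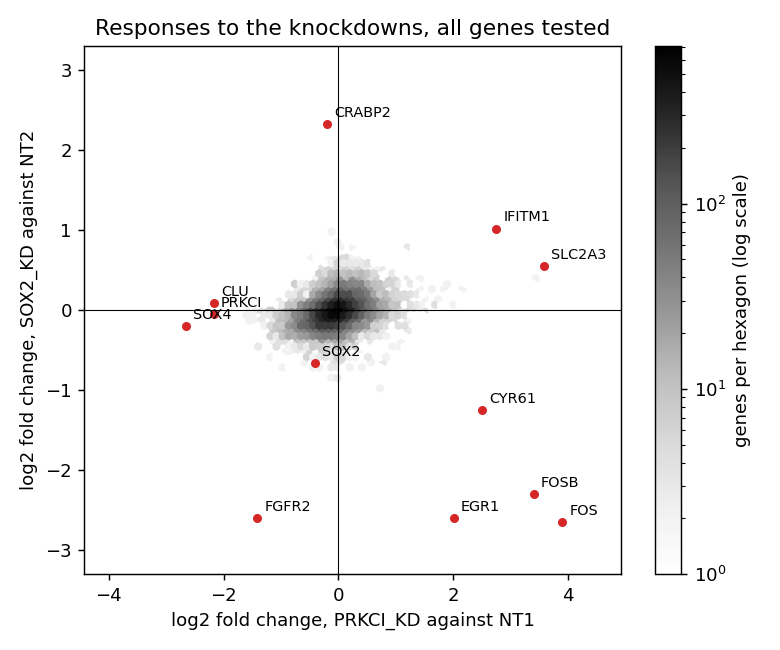
Log2 fold change of each of the 19777 genes tested in PRKCI_KD against NT1 (horizontal) and SOX2_KD against NT2 (vertical), as hexagons shaded by the number of genes on a log scale, with named genes in red. FOS, FOSB, EGR1 and CYR61 lie in the lower right, with PRKCI_KD values from 2.01 to 3.90 and SOX2_KD values from -2.65 to -1.26.

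The control groups, which carry no knockdown, differed from each other more than either knockdown from its control. ALDH1A1, a retinaldehyde dehydrogenase gene, was at 0.03 RPKM in NT1 and 196 RPKM in NT2 (log2 fold change 7.58, SE 0.05, adjusted p = 2.1e-15), and the receptor gene PDGFRA was at 0.05 and 146 RPKM. COL5A2, a collagen gene, was at 0.76 and 224 RPKM. The receptor kinase gene AXL was at 141 RPKM in NT1 and 0.13 RPKM in NT2, S100A11 at 163 and 0.52 RPKM, and FXYD5 at 107 RPKM in NT1 and listed at 0 in NT2. In these genes the knockdowns lay far nearer to their own control than to the other, with ALDH1A1 at 0.01 and 192 RPKM and AXL at 206 and 0.13 RPKM.

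Between NT2 and NT1, 15477 of 19777 genes passed, 7126 higher and 8351 lower in NT2, and 4393 changed at least 2-fold. With quantile normalization 7935 were higher and 7465 lower. Of 23 genes of cholesterol and fatty acid synthesis, 20 were higher in NT2 and 2 lower (adjusted p = 1.5e-05, and adjusted p = 0.0158 with an estimated correlation). Of 22 hypoxia response genes, 18 were higher and 4 lower (adjusted p = 9.8e-05, and adjusted p = 0.0902 with an estimated correlation), and of 18 mesenchymal genes 13 were lower and 3 higher (adjusted p = 0.0196, and adjusted p = 0.224 with an estimated correlation). Of 16 AP-1 and immediate early genes, 11 were higher and 3 lower (adjusted p = 0.00708, and adjusted p = 0.471 with an estimated correlation), and of 19 ribosome biogenesis genes 14 were higher and 2 lower (adjusted p = 0.00528, and adjusted p = 0.404 with an estimated correlation). The unfolded protein and integrated stress response was also higher in NT2, with 15 of 20 genes higher and 2 lower (adjusted p = 0.00708 in camera). NRF2 targets (adjusted p = 0.00708) and ribosomal proteins (0.0364) passed as higher. TGF-beta and BMP signalling (0.0364) and Wnt targets (0.041) passed as lower. None of these further lists passed with an estimated correlation. Adjusted over the list alone, the counts of these lists were the same. The labels name H1299 for both groups and place them on different flow cells, so the groups differ in flow cell as well as in the samples themselves.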

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

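The tests of the hypoxia genes against scaling and against the control groups, and the correction for GC content and length, were chosen after the result or the data were seen; the regroupings of libraries were chosen before.

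A difference between groups singled out the following results, since the response to the PRKCI knockdown and the response to the SOX2 knockdown were tested against each other. In all, 5155 genes differed. The difference of the log2 responses was 6.55 for FOS, 5.70 for FOSB, 4.61 for EGR1, 3.76 for CYR61 and 3.03 for SLC2A3, and -2.46 for SOX4, -2.26 for CLU, -2.24 for ID1, -2.13 for CRH and -2.12 for PRKCI. When libraries were regrouped within both pairs, 2 of 100 splits drawn from 200 gave as many genes, the real one included, and the highest of the others gave 5700. That share is under 0.05, but it comes from the 91 splits that mixed NT1 with PRKCI_KD, which gave at most 30 genes. Of the 9 drawn splits that kept these groups apart, the real one included, all gave at least 3898 genes and 2 gave as many as the real one. The count therefore rests mainly on the PRKCI_KD labels, and the splits do not exclude chance for the labels of NT2 and SOX2_KD.

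For the comparisons of a pair of groups, the splits of 6 libraries are too few for a share under 0.05. The real split gave 8928 genes for PRKCI_KD against NT1 and the highest other 1, the real split gave 1618 for SOX2_KD against NT2 and the highest other 1, and the real split gave 15477 for NT2 against NT1 and the highest other 0. In each, 1 of 10 splits, the real one, gave as many genes. For SOX2_KD, same-numbered libraries were treated as pairs here, although the deviations set only replicate 1 apart. The 3 other splits that part as many of these pairs gave 0 genes, and the 6 that part fewer gave at most 1.

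The entries with a repeated name or a date, which the main fit left out, were also looked at. Of 991 such entries that passed the level filter, 377 changed in PRKCI_KD and 90 in SOX2_KD when they were kept. Of the genes tested in the main fit, 45.1% and 8.2% changed, so these counts do not set the left-out entries apart.

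The rise of all 22 hypoxia genes in PRKCI_KD was weighed further. Library scaling and a trend with GC content or transcript length are argued against as the whole cause, since the list's median log2 fold change stayed at 1.93 with quantile normalization and at 2.01 after the correction, beside 1.94 as reported. Leaving out single libraries gave medians of 1.91 to 1.98. The oxygen, density or nutrient state of the cultures at harvest stays open and cannot be told apart from an effect of PRKCI, since the labels give no density or time of harvest. The list's median difference of 1.21 between the control groups does not decide it, as those groups differ in most genes, and an effect of the knockdown on these genes stays a hypothesis. The state of the cultures stays open as well for the AP-1, stress response and lipid synthesis lists, which also moved upward in PRKCI_KD. Their median log2 differences between NT2 and NT1 were 1.39, 0.68 and 1.21.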

How the results depend on the processing

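Median-of-ratios scaling, keeping the left-out entries, restriction to genes expressed in both controls, the correction for GC content and length and the set of genes with whole reads were chosen after the data were seen; the others were chosen before. Where a value moved, the cause was not tested, except that stricter thresholds leave fewer calls by construction. Under quantile normalization, other level filters, other pseudocounts, voom and each pair alone, every total of genes stayed within 1.5 times the reported one, but with quantile normalization the lower genes fell from 913 to 573 in SOX2_KD and from 502 to 259 among the shared. The count for SOX2_KD against NT2 (1618) was 3419 with the replicate block, 551 at an adjusted p of 0.01, 8 with treat, 3754 with the GC and length trend removed (1482 on the same genes uncorrected), 4201 with both, and 681 to 2230 when single libraries were left out. Without SOX2_KD replicate 3 it was 681, replicate 2 691 and replicate 1 1075, and without NT2 replicate 2 856 and replicate 3 903. The count shared by both knockdowns (834) was 1934 with the block, 247 at 0.01, 2 with treat, 2116 with the trend removed (820 on the same genes uncorrected), 2424 with both, and 328 to 1144 when single libraries were left out. The lowest counts were 328, 340 and 545 without SOX2_KD replicates 3, 2 and 1, and 420 and 455 without NT2 replicates 2 and 3. The ratio to independent lists stayed between 1.79 and 4.08 in all of these but treat, and among 13551 genes at 1 RPKM or more in both controls 721 were shared. The difference between the responses (5155) was 2915 at 0.01 and 262 with treat. PRKCI_KD against NT1 (8928) was 517 with treat, 10768 with the block and 7734 to 9231 when single libraries were left out, and NT2 against NT1 (15477) was 6280 with treat. The fall of SOX2 in SOX2_KD (-0.66) had adjusted p = 1 with treat against 1.5-fold, on a fold change that the pseudocount makes smaller: the means were 1.48 and 0.56 RPKM, and the value was -1.25 with a pseudocount of 0.1 and -0.22 with 5.

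Gene lists past the threshold were 13 for PRKCI_KD (5 with an estimated correlation, 23 with fry) and 9 for SOX2_KD (0 with an estimated correlation, with 7 at an unadjusted p under 0.05; 20 with fry, 14 without the level filter). The block took the call of NKX2-1 in PRKCI_KD (adjusted p = 0.0576) and of the Wnt targets in SOX2_KD (0.0526), gave one to CD68 in PRKCI_KD (0.00203), and changed no other call of a named gene or list. Of 6928 other values of 243 called changes in named genes, 6449 kept direction and call, 478 lost the call and 1 changed sign: MT-ND6 in SOX2_KD, with a log2 fold change of 0 under quantile normalization. Changes not called in SOX2_KD that also changed sign included these: PRKCI (-0.05 as reported) was 0 with quantile normalization and -0.12 to 0.02 without single libraries, and NPM1 (0.01) was -0.04 with quantile normalization and -0.02 to 0.05 without single libraries. NFKB2 (0.01) was -0.05 to 0.07 without single libraries, including 0 without NT2 replicate 2, and S100A2 (0.07) was -0.01 (without NT2 replicate 3) to 0.13. CDKN1A (-0.02) was 0.04 with quantile normalization, 0.01 with median-of-ratios scaling, -0.04 to 0.01 without single libraries and 0.05 with the trend removed, with or without the block. Without the 23 genes that lack whole reads, the counts were 8905, 1602, 5146 and 819 (shared). A planned count model was not run on these RPKM values; voom was run on the recovered reads. At the read depths used (77.05 M reads or more per library), simulated 1.5-fold changes were found in 89.6% (PRKCI_KD) and 82.1% (SOX2_KD) of the changed genes. Those genes were drawn from the ones at 1 RPKM or more in the control.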

Other observations

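The tests of flow cell and of scaling for the control groups, of the windows of neighbouring genes, of the number of genes a gain would cover, of the gene length and of the fixed lists for the values that are not whole reads were chosen after the result was seen; the neighbours of PDGFRA and the split of reads were predicted before.

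Some genes that the report does not name in this comparison were abundant in a single pair of groups and under 0.1 RPKM in the other. The adhesion receptor gene CD44 was at 33.4 RPKM in NT1 and 25.2 RPKM in PRKCI_KD, FLNC, which encodes a filamin, was at 69.1 and 87.5 RPKM, and the homeobox gene HOXB7 was at 43.5 and 32.0 RPKM. In the other pair, the surface marker gene THY1 was at 22.4 RPKM in NT2 and 17.9 RPKM in SOX2_KD, and LDOC1 and SLFN11, a gene of the DNA damage response, were at 46.8 and 14.9 RPKM in NT2. The matrix gene TNC was at 33.5 and 13.7 RPKM in NT1 and PRKCI_KD.

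Among the other AP-1 and immediate early genes, JUNB rose by 1.48 in PRKCI_KD and fell by 0.87 in SOX2_KD, and IER2 rose by 0.54 and fell by 0.92. KLF2 rose by 0.95 and fell by 0.49, while JUN fell by 0.77 in SOX2_KD and did not pass in PRKCI_KD.

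The first pattern weighed here is that the control groups differ in most genes, and scaling is argued against, with 77.9% of genes still differing with quantile normalization. A difference of flow cell, lane or library batch is argued against as the whole cause, since 36 genes were at 10 RPKM or more in all 6 libraries of NT1 and PRKCI_KD and under 0.1 RPKM in all 6 of the other pair, and 19 the other way, while no gene did so within either pair. A copy number gain around PDGFRA is argued against as the cause of so wide a difference, since it would cover 18 other measured genes within 2 Mb while 15477 differ; the median log2 difference of those neighbours, 0.57, met the value predicted for a gain, but 7.2% of 14291 windows of as many neighbouring genes reach it. Of these neighbours, 11 were higher in NT2, among them AC098587.1 (8.70) and FIP1L1 (3.52), and 3 were lower, among them NMU (-1.21), so a gain there as a part of the difference stays open. A hypothesis is that the pairs, all labelled H1299, may hold different cell populations, which genotypes of the lines could test and which these values alone do not show.

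The second pattern is that the values of 23 genes are not whole reads. A different length or a rounding of the whole gene is argued against, since for 19 of them a single length makes at least 5 libraries whole and leaves others not, and so is a split of reads between overlapping genes, since only 6% of the values that are not whole lie on a multiple of 1/2 to 1/5 of a read. Values set apart from the read counts in genes of the pathways under study may explain it: 43.5% of these genes are on the lists fixed beforehand against 1.44% of all genes checked, a ratio of 30.1 (Fisher's exact test across genes, two-sided, p = 3.49e-13). Of 69 triplets of libraries of these genes, 6 (8.7%) lay in the lower 0.05 tail of the spread given by counting alone. Of the triplets of other genes, 370 of 67589 (0.55%) did so (Fisher's exact test, p = 2.53e-06). Counting alone places a share of 0.05 in that tail, and replicates of other genes vary by more than counting noise. The 8.7% therefore shows a smaller spread than in other genes, not one below what counting allows. That values were set apart from the read counts is a hypothesis found and tested on the same values. No biological explanation was tested, and the raw reads, not used here, would decide it.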
